A study of Mus musculus with 2 samples.

How the data were processed

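Total RNA of remote left ventricle was analysed from 2 deposited samples, 1 per genotype. Libraries were made with a stranded total RNA kit, per the labels' protocols. HISAT2, Bowtie2 and the build mm10 are named without versions or roles, per the submitters' processing notes. The counting program, the annotation release and any use of strand are not given in the sources used here.

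The authors deposited a table of 36780 RefSeq transcripts with 24542 gene symbols. Per the file headers it holds a read count and an FPKM value for each library, and the length of each transcript in bases as another property. The deposited counts were whole numbers. The deposited FPKM values followed the counts over transcript length and library total, with a ratio to the recomputed FPKM from 0.962 to 0.988 over transcripts with at least 50 reads. How reads shared by isoforms or near-identical genes were divided into counts is not given in the sources used here, so transcript-level values are less certain than gene sums. The 3 columns whose names begin with C were given to the control sample, after the initial of the genotype in its title, and the 3 whose names begin with KO to the knockout sample. Gene coordinates are those of the table (mm10).

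The design fixed before the data were examined took 1 library per genotype, as the labels list, and had no test. It set a rule of size (at least 2-fold, with at least 1 CPM in a genotype and 20 reads in all, and a pseudocount of 1 CPM) on counts summed per gene symbol and per genotype, scaled by library total and TMM factor. The table turned out to hold 3 libraries per genotype. Libraries of a genotype differed far beyond counting error, with a median chi-square per degree of freedom from 3.88 to 19.1 over genes against 0.455 for repeat runs. A test across the 6 libraries was therefore added after the data had been seen. It used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr, Benjamini-Hochberg adjustment) on counts summed per gene, and genes with an adjusted p under 0.05 are said to have risen or fallen. Nothing in the labels says that the libraries came from separate animals, so the p-values measure only the spread between these libraries, which may be technical.

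Of the 44 gene lists fixed before the data were examined, 961 of 1011 entries were found in the table. The list of mitochondrially encoded genes had 0 entries there and was not analysed here, and 2 genes that the lists or the rule below cover, and the calls of 1 list that holds one of them, are not reported here. Lists were tested with fry (in a single direction, and in either direction) and camera in limma 3.58.1, and their members were also adjusted over the list alone. The medians of summed reads were placed among 10000 random lists matched in 20 expression bins. The rule for named genes took Nmrk2, the 10 highest and the 10 lowest summed folds among genes with a mean of at least 10 CPM (leaving out predicted genes, clone names, pseudogenes and small RNAs), up to 4 members of each list with the largest fold at a mean of at least 5 CPM (up to 8 for NAD synthesis and cardiac stress), Xist and 4 Y-linked genes, and the 5 most abundant genes of each genotype. Genes outside this rule were chosen after their values had been seen. These are Atcayos, Nmrk1, Kcnj2, Kcnj12, Atp5f1, Pfkfb1, Sod3, Gstm1, Cx3cl1, Pcolce, Serpinf1, Gsn, Pdgfrb, Tnnt3 and Gpd1, and in the closing section Myl4, the genes its opening names and a list of lung markers.

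Depth ran from 22377348 to 33086384 reads per library, and a count of 0 allows up to 3 reads. Intervals on read counts and such limits cover counting error only. The intervals of medians in the closing section resample genes instead. They treat genes as independent and leave out the spread between libraries. Test and rule were checked on simulated counts, 3 libraries against 3, for 14466 genes of which 100 were changed 2-fold and 100 were changed 4-fold. The test recovered 33 of the former and 94 of the latter and called 10 unchanged genes, and the rule of size passed 43, 100 and 186. All changed genes had a mean of at least 10 CPM, so recovery of less abundant genes was not checked. Alternatives were other scalings, abundance filters, pseudocounts and fold limits, the deposited FPKM, single transcripts, DESeq2 1.42.0, limma on log2(FPKM + 1), a block for the library number, thinning to equal depth, and leaving out each library in turn.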

Results

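The series measured total RNA from the left ventricle of male C57BL/6 mice 7 days after the left anterior descending coronary artery had been tied off permanently, a model of myocardial infarction. Only remote muscle was sequenced, the scar and its border having been cut away according to the labels. Mice lacking NRK-2, a nicotinamide riboside kinase of muscle that is encoded by Nmrk2 and feeds NAD synthesis, were compared with littermate controls. The labels list 1 sample per genotype, but the deposited table holds 3 numbered libraries for each, called here control 1 to 3 and KO 1 to 3. The control libraries held 22377348, 22794731 and 22831189 counted reads, and the libraries labelled KO held 28523593, 33086384 and 26975513. Expression is given as CPM (read counts scaled to the library total and a TMM factor), as mean ± SD over the 3 libraries of a genotype, and log2 fold changes are knockout over control.

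The targeted gene was examined first. Nmrk2 (gene ID 69564) lies on chromosome 10 from 81198170 to 81202037 (mm10). The 3 control libraries held 308, 270 and 118 Nmrk2 reads, or 15.1, 13.0 and 4.79 CPM. The library labelled KO 2 held 9 reads (0.252 CPM), and that labelled KO 3 held 0 reads, which allows up to 0.110 CPM. The library labelled KO 1 held 808 reads, 27.9 CPM, more than any control library and against its label. With it, the means were 11 ± 5.46 CPM in control and 9.39 ± 16.0 CPM in knockout (SD, n = 3 libraries each), and the gene did not pass edgeR's quasi-likelihood test (log2 fold change -0.23, SE 1.70, adjusted p = 0.952). With the reads summed per genotype the ratio of knockout to control was 0.842 (95% Clopper-Pearson interval 0.760 to 0.933, counting error only). The summed log2 fold change of -0.23 became -3.36 without KO 1, 0.42 without KO 2, 0.23 without KO 3, 0.07 without control 1, -0.06 without control 2 and -0.63 without control 3. Every direction given here for the knockout therefore rests on libraries labelled knockout, 1 of which held more reads of the gene than any control library.

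**Figure D1:**
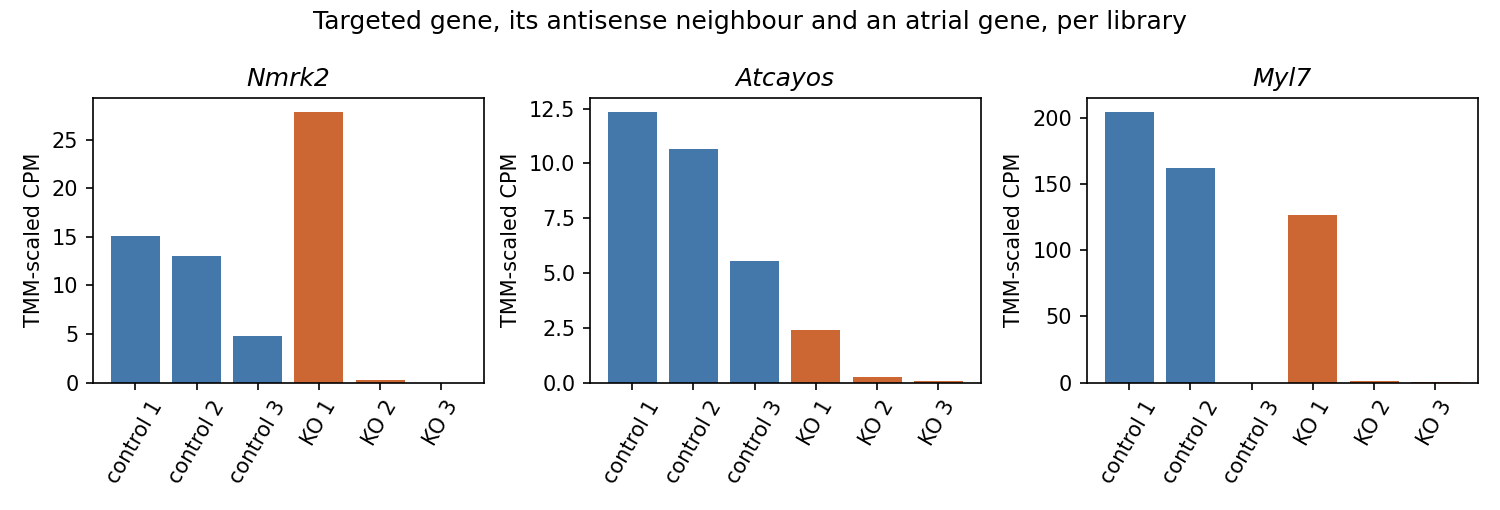
Bars give the TMM-scaled CPM (linear axes from 0) of Nmrk2, of the overlapping antisense gene Atcayos and of the atrial myosin light chain gene Myl7 in each of the 6 libraries, control in blue and labelled knockout in orange. Nmrk2 reached 27.9 CPM in the library labelled KO 1, whereas Atcayos was at 2.38 CPM there and at 5.56 CPM or more in each control library.

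Atcayos (gene ID 69678, chromosome 10), an antisense transcript whose locus spans Nmrk2, was at 12.4, 10.6 and 5.56 CPM in the control libraries and at 2.38, 0.252 and 0.073 CPM in those labelled KO 1, 2 and 3. It was lower in each library labelled KO than in any control library, but did not pass edgeR's test (log2 fold change -3.40, adjusted p = 0.111). Whether the authors' counting used strand is not given in the sources used here, so reads of these overlapping genes may not be separable. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had reads in every one of the 6 libraries, with Ddx3y at 143 CPM or more, and Xist had 0 reads in all 6, in keeping with the male labels.

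Across the transcriptome, of 14466 genes tested over the 6 libraries, 378 rose and 157 fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 252 of the former and 110 of the latter by at least 2-fold. Among the genes named by the fixed rule, C1qtnf3, a secreted protein related to C1q and TNF, rose from 4.04 ± 2.78 to 100.4 ± 24.7 CPM, and Col8a2, a chain of type VIII collagen, rose from 14.5 ± 3.81 to 230.3 ± 62.4 CPM (adjusted p = 0.0144 and 0.00899). The carboxylesterase Ces1d fell from 127 ± 32.9 to 23.7 ± 2.45 CPM, the ephrin Efnb3 from 54.0 ± 19.9 to 9.61 ± 4.15 CPM, the muscle fructose-bisphosphatase Fbp2 from 25.9 ± 10.8 to 5.14 ± 2.23 CPM and the orphan receptor Gpr22 from 112 ± 19.8 to 26.7 ± 9.23 CPM (adjusted p = 0.00929, 0.0348, 0.0483 and 0.0223). The number of calls changed strongly when a single library was left out. It was 47 without control 1, 25 without control 2, 3628 without control 3, 88 without KO 1, 47 without KO 2 and 3 without KO 3. Genes at an unadjusted p of edgeR's test under 0.05, 3744 with all libraries, numbered 2628, 2417, 5907, 2952, 2265 and 3358 in the same order. Fewer libraries also leave the test less power, so a lost call alone does not show that the library left out carried it. All 535 genes kept their direction in each of these fits, as is likely for genes chosen on the same libraries. Of the 40 genes named by the rule that passed, 39 lost their call in at least 1 of these 6 fits, Ltbp2 being the exception. Col8a2 lost it without KO 3, C1qtnf3 without KO 2 or KO 3, Ces1d without control 2 or KO 3, Gpr22 without control 1, control 2, KO 1 or KO 3, and Efnb3 and Fbp2 without any library other than control 3.

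Many extracellular matrix genes rose. Of 44 measured members of the matrix and fibrosis list, 25 rose and 0 fell (39 and 0 adjusted over the list alone), all 44 had a higher fitted level in the libraries labelled knockout, and the median log2 fold change was 1.77. Ltbp2, a protein of microfibrils, rose 12.9-fold from 52.3 ± 8.59 to 673 ± 104 CPM (log2 fold change 3.69, SE 0.20, adjusted p = 0.0031 by edgeR). Col11a1, a fibrillar collagen chain, rose from 5.19 ± 3.32 to 96.6 ± 46.5 CPM, Col8a1 from 125 ± 57.7 to 1263 ± 123 CPM and Cilp, a matrix protein of activated cardiac fibroblasts, from 76.4 ± 28.5 to 789 ± 298 CPM. The main fibrillar collagens Col1a1, Col1a2 and Col3a1 did not pass, with Col1a2 at 2473 ± 1180.3 against 6876 ± 1737 CPM (adjusted p = 0.099). The basement membrane and integrin list had a smaller median log2 fold change. Of 29 members 9 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 0.56. Among them the collagen chain Col4a2 rose from 673 ± 83.7 to 1493 ± 101 CPM and the integrin Itgb5 from 176 ± 29.0 to 485 ± 81.7 CPM, and Col4a1 and Col6a1 rose too.

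Both lists passed fry, which is used here, unless called mixed, to test whether a set's genes move on balance in a single direction (adjusted p = 0.0211 for matrix and 0.0170 for basement membrane). They lost the call with the library number as a block (adjusted p = 0.123 for each). Fry's mixed test, which counts changes in either direction, was passed by both (adjusted p = 0.00243 and 0.000289), as by 26 of the 43 lists. Both also passed the mixed test with the block (adjusted p = 0.0277 for each, 4 lists in all) and without each library in turn (at most 0.0164 and 0.0106). Both also passed camera, which compares a list with the other genes, at its preset correlation (adjusted p = 5.19e-55 and 5.07e-09), but not with an estimated correlation (adjusted p = 0.308 for both). The matrix list had 5 members past the test without control 1, 3 without control 2, 39 without control 3, 8 without KO 1, 4 without KO 2 and 2 without KO 3, and the basement membrane list 0, 0, 15, 1, 0 and 0. Fry's adjusted p for matrix lay from 0.0631 (without control 2) to 0.102 (without KO 1) in these fits, and that for basement membrane from 0.000757 (without control 3) to 0.102 (without KO 1), above 0.05 in the 5 fits other than that without control 3.

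**Figure D2:**
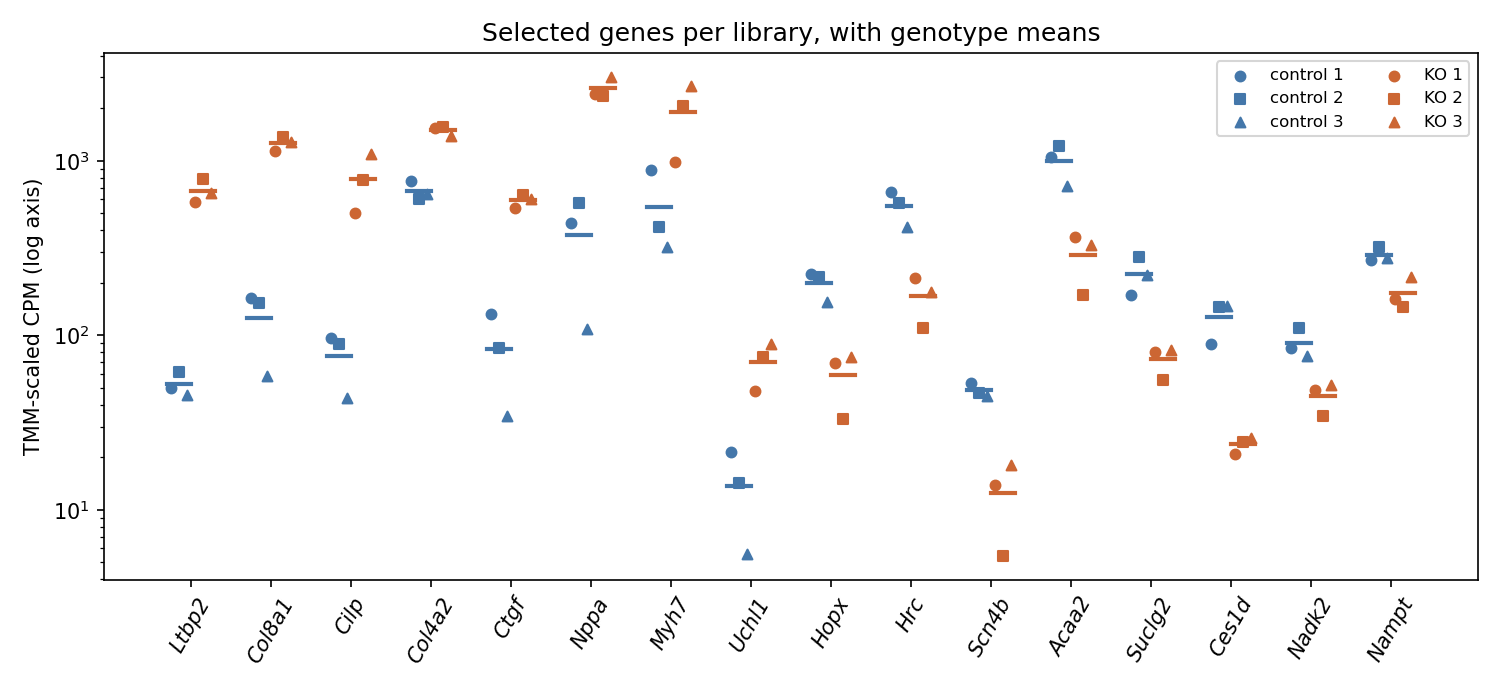
Points give TMM-scaled CPM per library on a log axis (control blue, labelled knockout orange, the marker shape giving the library number) and lines the mean of each genotype, for 16 genes named by the fixed rule. The 3 libraries labelled KO lie above all 3 controls from Ltbp2 to Uchl1 and below them from Hopx to Nampt, and Nppa, Myh7, Scn4b and Nampt did not pass the test.

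Genes that mark mechanical and hypertrophic stress of the heart were mostly higher. Of 17 measured members of the cardiac stress list, 2 rose and 1 fell (9 and 1 adjusted over the list alone), with a median log2 fold change of 1.10. Ctgf, a matricellular growth factor that is also on the matrix list, rose from 83.6 ± 48.5 to 593 ± 54.1 CPM, and the deubiquitinase Uchl1 rose from 13.7 ± 7.88 to 70.7 ± 21 CPM. Hopx, a homeodomain cofactor, fell from 198 ± 37.7 to 59.1 ± 22.5 CPM. Nppa, which encodes atrial natriuretic peptide, was at 374 ± 239 against 2597 ± 369.8 CPM and missed the threshold (log2 fold change 2.80, SE 0.58, adjusted p = 0.051 by edgeR). Gdf15, Myh7, Rcan1 and Xirp2 missed it too, with adjusted p = 0.0773, 0.0898, 0.069 and 0.0764. Nppa is also an atrial marker. It was at 442.5 and 571.6 CPM in control 1 and control 2, which carried atrial transcripts, and at 108.0 CPM in control 3. The libraries labelled KO 1, 2 and 3 were at 2418.5, 2349.7 and 3021.8 CPM. Whether atrial tissue added to the spread of Nppa in control was not tested. The list did not pass fry (adjusted p = 0.169), and its camera call (adjusted p = 3.03e-05) was lost with an estimated correlation (adjusted p = 0.64). Ctgf, Uchl1 and Hopx lost their calls without any library other than control 3, and without control 3 the list had 8 risers and 1 faller.

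Contractile and ion channel genes had median log2 fold changes below 0, with few calls. Median levels of contractile genes relative to the mean of all libraries overlapped, control 3 (-0.169) being as low as KO 1 (-0.168) and KO 3 (-0.128). For ion channel genes control 3 (0.053) lay above the libraries labelled KO (-0.185, -0.742 and -0.212). Of 27 contractile and calcium handling genes 0 rose and 1 fell (0 and 8 adjusted over the list alone, median -0.70). It was Hrc, a calcium-binding protein of the sarcoplasmic reticulum, which fell from 551 ± 125 to 167 ± 52.3 CPM. The troponin gene Tnni3 was at 3788 ± 1085 against 1317 ± 461 CPM and the phospholamban gene Pln at 8574 ± 1954 against 3543 ± 1162 CPM (adjusted p = 0.0664 and 0.0787). Of 26 ion channel and conduction genes 0 rose and 2 fell, the inward rectifier channels Kcnj2 and Kcnj12 (1 and 12 adjusted over the list alone, median -0.78). The sodium channel subunit Scn4b, at 48.5 ± 4.51 against 12.5 ± 6.43 CPM, missed the threshold (adjusted p = 0.0504). Cardiomyocyte markers, which share members with the contractile list, had a median of -0.99 over 15 genes, with 0 past the test over all genes and 1 riser and 10 fallers adjusted over the list alone. None of the 3 lists passed fry (adjusted p = 0.286, 0.169 and 0.289 in the order given). Their camera calls (adjusted p = 1.48e-07, 4.93e-08 and 3.03e-05) were lost with an estimated correlation (adjusted p = 0.726, 0.64 and 0.727). Without control 3, 13 contractile and 14 ion channel genes fell. Without any other library 0 contractile genes fell, and 1 ion channel gene fell without KO 2 and 0 without the others.

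Most genes of mitochondrial fuel use had lower fitted levels in the libraries labelled knockout, with few calls. Each of the 69 nuclear-encoded oxidative phosphorylation genes had a lower fitted level in the libraries labelled knockout (median log2 fold change -1.0), but only 2 fell over all genes tested, the cytochrome oxidase subunit Cox7a1 and the ATP synthase subunit Atp5f1, against 67 adjusted over the list alone. Of 41 genes of fatty acid oxidation and uptake 6 fell and 0 rose (34 and 0 adjusted over the list alone, median -1.08). Acaa2, the thiolase that ends each round of beta-oxidation, fell from 997 ± 258 to 287 ± 103 CPM, and Eci1, an enoyl-CoA isomerase, fell from 287 ± 73.3 to 101 ± 30.2 CPM. Of 20 genes of the tricarboxylic acid cycle 1 fell (19 adjusted over the list alone, median -0.98), the succinate-CoA ligase subunit Suclg2, from 224 ± 55.2 to 72.9 ± 15.0 CPM. Of 17 genes of branched-chain amino acid and ketone use 6 fell and 0 rose (14 and 1 adjusted over the list alone, median -0.86). Among them Ppm1k, the phosphatase of the branched-chain ketoacid dehydrogenase, fell from 282 ± 51.9 to 106 ± 32.6 CPM and Dbt, a subunit of that enzyme, from 108 ± 15.3 to 43.5 ± 10.1 CPM. Over these 4 lists, median levels of members relative to the mean of all libraries were lowest in KO 2 (-0.89 to -1.04), and control 3 (-0.01 to 0.18) lay between the other control libraries and the libraries labelled KO. None of the 4 lists passed fry (adjusted p = 0.155, 0.129, 0.154 and 0.152 in the order given), and their camera calls at the preset correlation were lost with an estimated correlation (adjusted p = 0.64 for each). Without control 3, 67, 33, 19 and 14 members of the 4 lists fell. Without any other single library 0 members fell, except for 1 fatty acid gene without KO 1.

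The remaining metabolic lists held few calls. Of 36 genes of glycolysis and glucose use 1 rose, the lactate transporter Slc16a3, from 6.48 ± 2.43 to 23.6 ± 8.47 CPM, and 1 fell, Pfkfb1, which sets fructose 2,6-bisphosphate (3 and 10 adjusted over the list alone, median -0.48). The mitochondrial ribosome and mtDNA maintenance list had a median of -0.64 with 0 of 23 members past the test (0 risers and 16 fallers adjusted over the list alone). Of 19 genes of mitochondrial dynamics and mitophagy 0 rose and 1 fell, the inner membrane protease Oma1, from 38.6 ± 6.96 to 21.2 ± 1.81 CPM (0 and 2 adjusted over the list alone, median -0.61), and the mitophagy kinase Pink1 stood at 692 ± 188 against 311 ± 49.7 CPM (adjusted p = 0.0572). Creatine and energy buffering genes went both ways, 7 having a higher and 7 a lower fitted level (median -0.08, with 0 of 14 past the test, and 2 risers and 5 fallers adjusted over the list alone). These 4 lists did not pass fry (adjusted p = 0.358, 0.155, 0.289 and 0.541), and camera's calls of the first 3 were lost with an estimated correlation (adjusted p = 0.832, 0.64 and 0.832). Slc16a3 and Oma1 lost their calls without any library other than control 3, and without control 3 there were 4 risers and 18 fallers in glycolysis and 12 fallers in mitochondrial dynamics. Mitochondrially encoded genes were not analysed here.

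Genes of NAD synthesis, the pathway NRK-2 belongs to, went both ways. Of 19 measured genes of NAD synthesis and salvage 0 rose and 1 fell (0 and 4 adjusted over the list alone), with a median log2 fold change of -0.22. The median was the value of Nmrk2 itself, which depends on KO 1, and without Nmrk2 it was -0.26, with 7 genes at a higher and 11 at a lower fitted level. The mitochondrial NAD kinase Nadk2 fell from 90.6 ± 17.5 to 45.1 ± 9.28 CPM (adjusted p = 0.0498 by edgeR). The mitochondrial transhydrogenase Nnt was at 1093 ± 263 against 467 ± 109.6 CPM, Nampt, the rate-limiting enzyme of NAD salvage from nicotinamide, at 289 ± 28.3 against 174 ± 36.8 CPM and Nmnat3, a mitochondrial adenylyltransferase, at 20.9 ± 6.83 against 10.3 ± 0.862 CPM (adjusted p = 0.058, 0.072 and 0.0788). Nmrk1, the other riboside kinase gene, was at 5.61 ± 1.5 against 6.21 ± 1.82 CPM (adjusted p = 0.81). Nmnat1, Nnmt, Afmid and Naprt had adjusted p = 0.215, 0.406, 0.159 and 0.209. Of 18 NAD-consuming enzymes 1 rose, the tankyrase Tnks, from 99.5 ± 4.48 to 143 ± 7.50 CPM, and 0 fell (1 and 1 adjusted over the list alone, median 0.02). The mitochondrial deacylases Sirt3 and Sirt5 and the polymerase Parp1 did not pass (adjusted p = 0.148, 0.141 and 0.0614). NAD synthesis passed fry's mixed test, which counts changes in either direction (adjusted p = 0.0271), but not with the library number as a block (adjusted p = 0.158) or without any library other than control 3 (adjusted p = 0.0732 to 0.14). Neither list passed fry in a single direction (adjusted p = 0.135 and 0.842) or camera at its preset correlation (adjusted p = 0.174 and 0.821). Nadk2 and Tnks lost their calls without any library other than control 3, and without control 3 the lists had 2 risers and 5 fallers, and 2 risers and 3 fallers.

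Stress and inflammatory lists held few calls. Of 23 immediate early genes 1 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.49), the transcription factor Egr2, from 2.17 ± 0.346 to 12.9 ± 2.52 CPM, which lost its call without control 2 or KO 3. Of 27 antioxidant genes 2 rose, the extracellular enzymes Gpx3 and Sod3, and 2 fell, the glutathione transferases Gsta3 and Gstm1 (4 and 7 adjusted over the list alone, median 0.04). Gpx3 rose from 78.4 ± 10.1 to 202 ± 15.2 CPM, and the list had 1 call without KO 1 and 0 without any other library than control 3. Of 27 genes of the integrated stress and unfolded protein response 1 rose, the mitochondrial folate enzyme Mthfd2, and 1 fell, Herpud1 (3 and 3 adjusted over the list alone, median 0.04). Of 27 chemokines and cytokines 1 rose, the fractalkine gene Cx3cl1, and 0 fell (1 and 0 adjusted over the list alone, median 0.37), and Spp1, which encodes osteopontin, was at 43.0 ± 37.2 against 223 ± 157 CPM (adjusted p = 0.169). Mthfd2, Herpud1 and Cx3cl1 lost their calls without any library other than control 3, and without it the lists of immediate early, antioxidant, stress response and chemokine genes had 7, 4, 3 and 1 risers and 0, 7, 2 and 0 fallers.

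Heat shock proteins (median -0.24), the circadian clock (median -0.23), angiogenesis and hypoxia (median 0.09), apoptosis (median 0.35), the cell cycle (median 0.70), the interferon response (median 0.40), antigen presentation (median 0.44) and cytosolic ribosomal proteins (median 0.06) had 0 members past the test. Cell cycle genes differed within the knockout group, the mitotic kinase gene Cdk1 being at 27.1, 22.5 and 8.58 CPM in the libraries labelled KO 1, 2 and 3 and at 7.23 to 9.17 CPM in control. None of the lists of stress and inflammation passed fry in a single direction. The mixed test was passed by immediate early (adjusted p = 0.00621), antioxidant (0.00767), stress response (0.00961), angiogenesis (0.0189), circadian (0.0201) and ribosomal protein genes (0.0368), and by none of these with the library number as a block. Leaving out each library in turn ended that call for stress response genes without KO 2, for angiogenesis without control 2 or any library labelled KO, for circadian genes without control 1, control 2 or KO 1, and for ribosomal proteins without control 1, control 2, KO 1 or KO 2. Camera's calls of the immediate early, interferon, cell cycle and apoptosis lists were lost with an estimated correlation (adjusted p = 0.64, 0.832, 0.832 and 0.725). In all, 18 of the lists measured had 0 of their members past edgeR's test over all genes. Of their 327 entries, 39 were higher and 51 lower at an unadjusted p under 0.05, and DESeq2 called 22 higher and 40 lower. The shares over all 14466 genes tested were similar, with 3744 at an unadjusted p of edgeR's test under 0.05 and 2445 called by DESeq2.

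Markers of the cell types of the ventricle did not move together. Of 14 fibroblast markers 3 rose and 2 fell (6 and 2 adjusted over the list alone, median 0.86). Mfap5, a microfibril protein, rose from 64.0 ± 15.5 to 267 ± 29.9 CPM, and Pcolce and Serpinf1, both secreted, rose too, whereas the ferritin receptor Scara5 fell from 37.9 ± 9.79 to 14.9 ± 1.78 CPM and the actin-severing Gsn fell as well. Of 20 macrophage and monocyte markers 2 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.75), the fractalkine receptor Cx3cr1, from 19.2 ± 1.55 to 63.8 ± 12.3 CPM, and Ms4a7, from 11.9 ± 5.39 to 52.4 ± 8.50 CPM. Cd163, a marker of resident macrophages, was at 35.9 ± 20.5 against 15.9 ± 1.33 CPM (adjusted p = 0.108). Of 15 endothelial markers 0 rose and 1 fell (0 and 1 adjusted over the list alone, median 0.04), the water channel Aqp1, from 358 ± 12.7 to 190.1 ± 41.4 CPM. Smooth muscle and pericyte markers had 1 riser, Pdgfrb (median 0.08), Schwann cell and neuronal markers 1 riser, Pmp22 (median -0.45), skeletal muscle markers 1 riser, the fast troponin gene Tnnt3 (median 0.84 over 5 genes), and adipocyte markers 1 faller, Gpd1 (median -0.48). Endocardial and lymphatic (median -0.38), epicardial (median -0.44), T and NK cell (median -0.28), B cell (median -1.85), neutrophil (median 0.16), erythroid and platelet (median 0.10) and atrial markers (median -0.24) had 0 members past the test. None of the cell type lists passed fry in a single direction (adjusted p = 0.155 for fibroblasts and 0.358 for macrophages), and camera's calls of the fibroblast and macrophage lists were lost with an estimated correlation (adjusted p = 0.64 and 0.832). Fry's mixed test was passed by 9 of the 15 marker lists, among them fibroblast (adjusted p = 0.00243), smooth muscle (0.00243), skeletal muscle (0.000289) and macrophage markers (0.0172). Without control 1, 2 and 3 and KO 1, 2 and 3 in turn, 5, 3, 10, 4, 3 and 4 marker lists passed it, and 2 with the library number as a block. The first 3 of these 4 lists passed without each library, and macrophage markers did not without control 2, KO 2 or KO 3 (adjusted p = 0.0608, 0.0894 and 0.0732). Over all 43 lists 26 passed it, and 13, 9, 34, 12, 9 and 15 without each library in the same order. Mfap5 lost its call without KO 3, Cx3cr1 without control 1, control 2 or KO 3, Ms4a7 without control 2 or any library labelled KO, and Scara5, Aqp1 and Pmp22 without any library other than control 3. Without control 3, 7 fibroblast markers rose and 2 fell, and 13 macrophage markers rose and 1 fell. The smooth muscle, adipocyte and skeletal muscle lists held 0 calls without any library other than control 3, apart from 1 skeletal muscle gene without control 2.

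Several marker lists separated libraries within a genotype rather than the genotypes. Relative to the mean of all libraries, B cell markers were 2.87 higher on the log2 scale in control 3 and 1.03 higher in KO 2, and lay below 0 in the other libraries, with the immunoglobulin joining chain gene Jchain at 549 CPM in control 3 and 137 CPM in KO 2. Adipocyte markers were 1.54 and 1.28 higher in these 2 libraries and neutrophil markers 1.58 and 1.12 higher, and the adiponectin gene Adipoq stood at 131 CPM in control 3. Atrial markers were 1.05, 0.88 and 1.45 higher in control 1, control 2 and KO 1, with Myl7 at 205, 162 and 127 CPM there and at most 1.15 CPM in the other libraries.

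**Figure D3:**
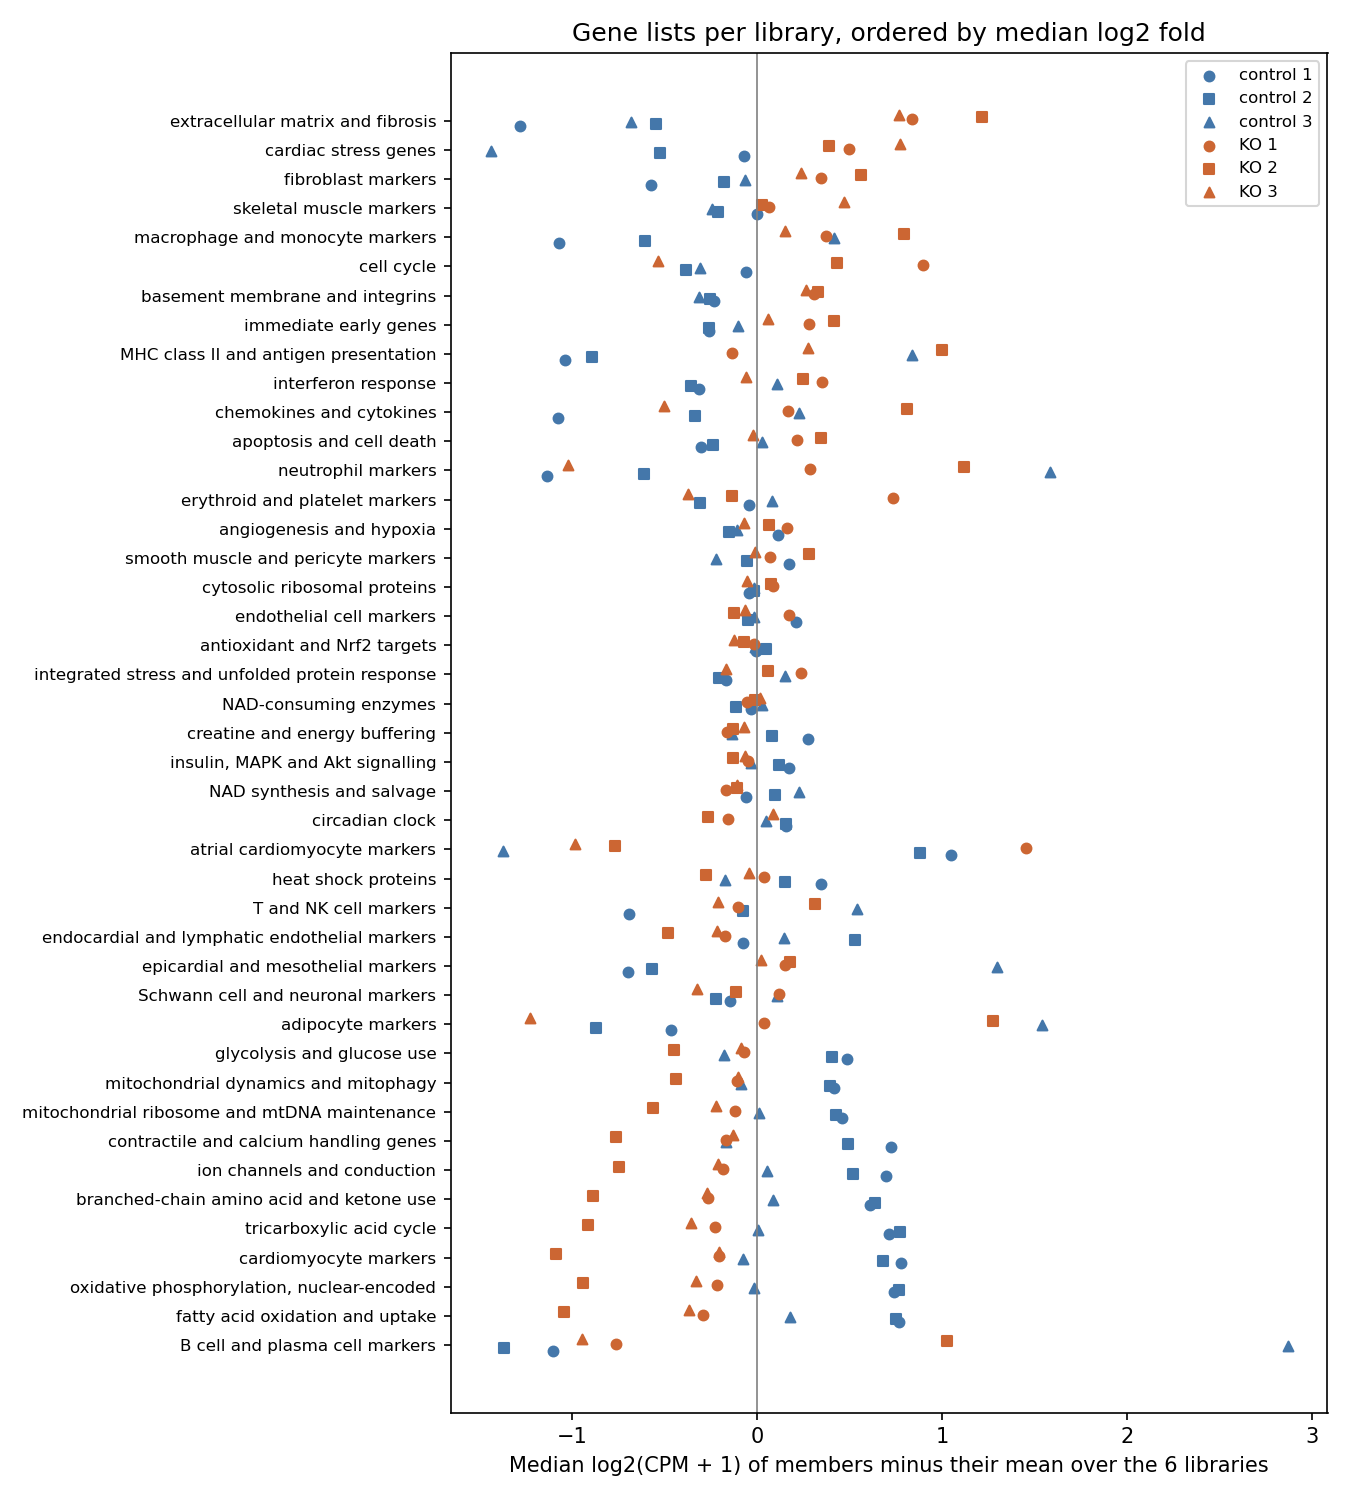
Each point gives, for a gene list and a library, the median over members of log2(CPM + 1) minus the member's mean over the 6 libraries (control blue, labelled knockout orange), with the 43 lists ordered by median log2 fold change. Matrix genes lay at -1.28, -0.54 and -0.68 in the control libraries and at 0.84, 1.21 and 0.77 in those labelled KO, while B cell markers were highest in control 3, at 2.87.

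By the rule of size fixed before the data were examined, on reads summed per genotype and with no test, 527 of 13872 expressed genes were at least 2-fold higher in the knockout sum and 485 at least 2-fold lower. These were 647 and 349 with library totals only, 649 and 347 with totals without ribosomal RNA genes, and 1011 and 802 without control 3. Drawing both sums from a common profile gave a median of 0 such genes with counting error alone, 143 with an added coefficient of variation of 0.2 and 2606 with one of 0.4. These assumed values are for a sum. edgeR's estimate between single libraries of a genotype was 0.325, and a sum of 3 separate libraries varies less than a single library. Of the 10 genes with the highest summed fold, 7 were read mainly in the library labelled KO 2. They were the surfactant genes Sftpc, Sftpa1 and Sftpb, and Slc34a2, Chil3, Cxcl15 and Hc, with Sftpc at 197 CPM in KO 2, 7.70 CPM in KO 3 and 0.241 CPM or less in the other libraries. Of the 10 lowest, Hba-a1, Hbb-bs and Sap18b have near-identical copies, between which the authors' counting could divide reads in either way. Summed with Hba-a2, Hba-a1 was at 452.5, 316.9 and 240 CPM in the control libraries and at 751.2, 205.2 and 123.7 CPM in those labelled KO, which overlap. Summed with Hbb-bt, Hbb-bs was still high in control 2 (358.3 CPM against at most 31.2 CPM elsewhere), so its fold rests on the count in that library. All haemoglobin genes together took 0.106%, 0.0730% and 0.0725% of reads in the control libraries. They took 0.209%, 0.0591% and 0.0349% in those labelled KO. Control 2 was therefore not high in haemoglobin reads as a whole, and a division of reads with other haemoglobin genes was not excluded. Marco, a marker of macrophages, was high in control 3 alone (55.9 CPM). The metalloproteinase inhibitor gene Timp4 was at 29.6 ± 8.57 against 6.53 ± 5.10 CPM and did not pass edgeR's test (adjusted p = 0.0785).

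The list medians of the summed reads were also placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. Of 43 lists measured, 26 lay outside the central 95% of random lists. The matrix list lay at the percentile of 100, with 39 of 44 members at least 2-fold higher and 0 at least 2-fold lower, and the fatty acid list at 0, with 26 of 41 at least 2-fold lower. NAD synthesis lay at 2.36 and NAD consumers at 56.4. The B cell list lay at 0, with a summed median of -1.5 that turned to 1.34 without control 3.

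The makeup of the libraries differed too. The 10 most abundant genes took 12.6%, 12.5% and 10.4% of reads in the control libraries and 9.37%, 8.80% and 9.75% in those labelled KO 1 to 3. The titin gene Ttn was the most abundant in both genotypes (31052 ± 6465 against 22575 ± 3695 CPM). Next in control came the contractile gene Myh6, the calcium pump gene Atp2a2, the oxygen-storage gene Mb and the contractile gene Actc1. Genes of the matrix list together took 1.02%, 2.36% and 2.84% of reads in control and 5.73%, 7.48% and 5.17% in the libraries labelled KO, the exact binomial interval being 7.47% to 7.49% for the highest of these.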

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

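The tests over 6 libraries, and every fit that leaves out a library, were chosen after the data had been seen. All 535 genes past the main test kept their direction wherever they were tested. That is likely for genes chosen on the same libraries, and is no separate support. Risers and fallers, 378 and 157, were 348 and 150 with median-of-ratios scaling, 413 and 220 with library totals only, 317 and 106 with all genes of at least 1 read, 484 and 302 with a mean of at least 10 CPM, 372 and 157 after thinning, 1116 and 1329 with DESeq2, and 524 and 348 with limma on log2(FPKM + 1). Leaving out 1 library gave 3 (without KO 3) to 1719 (without control 3) risers and 0 (without control 2 or KO 3) to 1909 (without control 3) fallers. Deviations of same-numbered libraries from their group means correlated at 0.238, -0.238 and -0.302 across genes. The highest correlation of a control library with one labelled KO was 0.507, for control 3 and KO 2. These values do not show pairing by column number, but with so few libraries they cannot exclude it. With the number as a block 6 genes rose and 0 fell, with 2838 at an unadjusted p under 0.05. The cause of these moves was not tested.

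The summed counts of 527 higher and 485 lower genes became 276 and 258 with a pseudocount of 5 CPM, 1579 and 1593 at 1.5-fold, 159 and 75 at 3-fold, and 1576 and 1292 over single transcripts, and the lower count became 245 with the deposited FPKM. Leaving out 1 library gave 377 (without KO 2) to 1011 (without control 3) higher and 367 (without KO 2) to 802 (without control 3) lower genes, a summed log2 fold change of Nmrk2 from -3.36 (without KO 1) to 0.42 (without KO 2), and 26 to 30 lists outside the central 95% of random lists. Scaling by library totals alone moved the median log2 fold change of all genes to 0.10, from 0.01 with TMM. Of 642 list medians under alternatives 595 moved by less than their spread between libraries (1 SD) and 46 by more, and that of B cell markers reversed without control 3, its range being -2.37 (without KO 2) to 1.34 (without control 3). A reversal was counted only for main medians of at least 1 in size. Smaller medians that changed sign would be among the 595 and 46. Over the fits that leave out a library, named genes lost a call 171 times and gained one 87 times, with 0 changes of direction among called genes. Genes with an isoform share difference above 0.3, 371 in all, were 108 at a difference above 0.5 and 200 at 500 reads or more. Alternatives with TPM, which the table does not list, and those on mitochondrially encoded genes were not run.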

Other observations

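Beyond the fixed lists, the genes with the lowest p-values, chosen after their values had been seen, included the following. Loxl3, a lysyl oxidase that cross-links collagen, rose from 23.9 ± 1.59 to 156 ± 13.5 CPM and the collagen-binding integrin Itga11 from 12.8 ± 1.78 to 70.1 ± 12.0 CPM in the libraries labelled knockout (adjusted p = 0.00182 and 0.00899 by edgeR). The secreted proteins Srpx2 and Pdgfrl rose from 20.2 ± 3.92 to 102 ± 13.0 CPM and from 4.97 ± 0.492 to 30.7 ± 5.91 CPM, and Nkd2, an inhibitor of Wnt signalling, from 6.97 ± 1.61 to 46.2 ± 7.95 CPM. Ddah1, which degrades the nitric oxide synthase inhibitor dimethylarginine, rose from 11.1 ± 3.57 to 125 ± 22.7 CPM. Within the matrix list, the periostin gene Postn rose from 719.8 ± 472 to 5163 ± 690.1 CPM and Thbs4, a matricellular protein, from 13.3 ± 7.26 to 122 ± 31.1 CPM. Loxl3 passed without each of the 6 libraries in turn, and Itga11, Srpx2, Pdgfrl, Nkd2 and Ddah1 passed except without KO 3. Postn lost its call without control 1 or any library labelled KO, and Thbs4 without any library other than control 3.

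Transcript shares within genes also differed. Of 4641 genes with several transcripts and enough reads, 371 had a transcript whose share of the summed reads differed by more than 0.3 between genotypes, and in 137 of these the libraries of the genotypes did not overlap. Over all 4641 genes they did not overlap in 671. Chance gives 10% for a transcript not picked by its difference, and more for these, each being the one that differed most in its gene. Of 4423 genes with at least 30 reads in each library, a gap above 0.5 between the genotypes' libraries occurred in 13, and in up to 8 for the other 9 ways to split the libraries 3 against 3. Reads shared by isoforms make such shares uncertain.

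All tests of explanations below were chosen after the pattern was seen, and the lung markers tested were listed before their values were seen. In the library labelled KO 1, Nmrk2 went against the label, and a swap with a control library would leave a control library without Nmrk2 reads, but the lowest control library held 118. Over the 88 genes called without KO 1, its position between the controls (0) and the other libraries labelled KO (1) was measured. The median was 0.83 (95% interval over resampled genes 0.79 to 0.86). This argues against a library of the control group under a wrong label, though not against an animal of another genotype with the same response. Mixed-in control RNA would bring Atcayos along, but Atcayos reads per Nmrk2 read were 0.085 (0.066 to 0.109) there and 0.818 to 1.16 in the controls. Atrial tissue may add Nmrk2 reads, since Nmrk2 reads per Myl4 read were alike in control 1, control 2 and KO 1, which carried atrial transcripts (0.0739, 0.0739 and 0.0884). Per Myl7 read, however, KO 1 stood above control 1 and control 2 (0.0739, 0.0802 and 0.22). KO 2 had the same ratio to Myl7 as KO 1 (0.22), but from only 9 Nmrk2 and 41 Myl7 reads, and 0.0404 per Myl4 read. KO 3 held 0 Nmrk2 and 6 Myl7 reads, too few to compare. Control 3 had 2.07 Nmrk2 reads per Myl4 read, so these values do not decide. Atrial tissue of a mouse without Nmrk2 transcript would bring no such reads. For KO 1 this explanation therefore also needs an allele that still gives reads, or an animal of another genotype. The source of the reads therefore stays open, and a knockout allele that keeps part of the transcript was not tested.

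The matrix list had a higher median and the lists of mitochondrial fuel use lower medians in the libraries labelled knockout. For the matrix genes, a lower share of cardiomyocytes would raise all other cell types alike and more fibroblasts of an unchanged kind their other markers as far, but the matrix median exceeded the endothelial one by 1.73 (1.42 to 2.23) and that of 9 fibroblast markers off the matrix list by 1.52 (0.37 to 2.76). These 95% intervals, from resampled genes, leave out the spread between libraries. For the fuel genes, a lower share of cardiomyocytes cannot be told apart from a fall within them, as these and cardiomyocyte markers had like medians (-1.01 and -0.96, difference -0.05, 95% interval -0.64 to 0.18), the endothelial one being 0.04. Border or scar tissue left in the dissections cannot be told apart from a stronger response of remote muscle, as both would raise the cardiac stress list (median 1.10), and the genotype stays open as well. Of the 10 splits of the 6 libraries 1, the real one, gave as many as 535 genes, the highest other giving 2, and 10 splits are too few for a share under 0.05, while the count fell to 3 without KO 3 and rose to 3628 without control 3.

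Surfactant and other lung genes were read mainly in the library labelled KO 2. Of 13 lung markers whose values had not been seen, 11 were highest there at 1 CPM or more, and 4 of the 13 also reached 1 CPM in a control library. Lung tissue or lung RNA in that library is a candidate source, with Sftpc at 197 CPM and Ager at 39.6 CPM there, though the labels describe remote ventricle after dissection. Whether it entered as tissue or in library preparation or sequencing stays open, and no biological explanation was tested.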
